A study of Homo sapiens with 9 samples.

How the data were processed

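RNA was sequenced from 9 samples of 1 human primary melanoma from 1 donor. Per the labels and the series design, 3 areas of the tumor were sectioned, and each section was microdissected into tumor center, tumor border and tissue adjacent to the tumor, which gave 3 libraries per region. How the boundaries between the regions were drawn is not given in the sources used here. The libraries of a region are therefore separate pieces of the same tumor and not separate donors. Every p-value over these regions measures the spread between sections of 1 tumor and is too small for any statement about melanomas in general.

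Per the labels' protocols, the tissue was formalin fixed and frozen, total RNA was extracted with the miRNeasy kit, and libraries were made with the TruSeq RNA Access kit, which enriches a cDNA library for coding exons with capture probes. The kit name in the labels carries the word for fixed and embedded tissue, while the tissue is called frozen, and this difference was not resolved. Capture by exon probes means that the level of a gene also depends on how well its probes work, so levels were compared between regions for a gene and not between genes. Fixed RNA is fragmented, and short fragments are harder to place uniquely. Per the submitters' processing notes, CASAVA 1.7, HISAT2 2.1.0 and HTSeq 0.9.0 were used with the GRCh38 build. Their settings, the annotation release and the use of strand in counting are not given in the sources used here. For that reason a gene and an overlapping or antisense partner could not be told apart.

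Each deposited file held the authors' read count per gene as whole numbers, not normalized, for 20320 gene identifiers, followed by 5 special rows that HTSeq writes. Those 5 were left out of library sizes and tests. Of all records in a library, 40.08 to 45.08% were counted in genes, 39.4 to 45.93% had more than 1 alignment, 4.96 to 9.53% lay outside annotated genes, 1.32 to 2.03% fell in more than 1 gene, 2.39 to 3.18% had too low an alignment quality and 1.08 to 1.53% were not aligned. Records with more than 1 alignment were not counted in any gene, so near-identical genes lose counts. Values for KRT6A, KRT6B, KRT6C, KRT14, KRT16, KRT17, HLA genes, MAGEA genes, C4A and C4B, the globin genes, TPSAB1 and TPSB2, HSPA1A and HSPA1B, immunoglobulin genes and ribosomal protein genes are uncertain on that account.

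Symbols came from a table of gene names for 20181 identifiers and from GENCODE release 29 for a further 107, while 32 had no symbol. Positions on GRCh38 were found in GENCODE release 29 for 20288 identifiers, and they are given 1-based. Because a person donated the tissue, genes of the Y chromosome and XIST were left out of all tests and tables. Counts per gene summed to between 11973820 and 15256326 per library, and 17164 to 19190 genes had at least 1 count. Replicate libraries of a region differed by far more than sampling noise, with a chi-square of 10.28 to 40.73 per gene, so none was a library deposited more than once. Sequencing reads are not independent molecules after PCR, and depth covers counting error only.

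Differential expression was tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, robust fit) with TMM scaling and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. A filter on low counts left 16209 genes. All 9 libraries entered 1 fit with region as the term, which left 6 residual degrees of freedom, and the biological coefficient of variation was 20.5%. The contrasts were center against adjacent tissue, border against adjacent tissue, center against border, any difference among the 3 regions, and border against the midpoint of the log2 levels of the other regions. A further count took genes called in both border contrasts with the border above, or below, both other regions. Levels are given as counts relative to library size (CPM) with TMM factors of 0.919 to 1.093, as mean ± SD over 3 libraries. The position of the border was the median over genes of its distance from adjacent tissue divided by the distance of the center from adjacent tissue, on log2 CPM.

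Before the data were examined, 44 gene lists with 698 members were fixed for cell types and processes that skin, tumor and immune tissue hold. They were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 44 lists. Alternatives were an estimated correlation for each list and fry, which tests whether the genes of a list move on balance one way without comparing them to other genes. For the members of each list the number of calls is given over all genes tested and, in addition, adjusted over the list alone. Also fixed in advance was the rule for named genes. It took the 8 largest rises and the 8 largest falls of each pairwise comparison among called genes with at least 20 CPM in the higher group and no overlap between the libraries of the groups. It added up to 4 members with the smallest p of each list described, and 22 genes given whatever their result. For the border it took the 6 highest and the 6 lowest genes. Some genes that this rule took are not reported here. Other genes are named as chosen after their values were seen.

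Alternatives fixed in advance were DESeq2 size factors, library size alone, scaling without the 50 most abundant genes, no filter, a mean count of 50 or more, DESeq2 1.42.0 and limma voom as other tests, section number as a replicate block, fits of only the groups compared, each library left out in turn and an adjusted p under 0.01. Added after the data had been seen were the log2 share of counts on 405 olfactory receptor genes as a covariate, with and without an estimated inter-gene correlation, and fits without the 4 libraries farthest from the others in that share. The latter fits kept 1 border and 1 adjacent tissue library. They cannot tell an effect of that share from the loss of replicates, so their counts are not given. Counts of calls were set beside those of 100 splits of the 9 libraries out of 280 possible ones, or of the 10 splits of 6 libraries. Exact permutation tests were used for single values. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the remaining steps.

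The fits were tested on simulated data with known changes before they were used. In the simulation of center against adjacent tissue over 15754 genes, edgeR recovered 50.5% of genes changed 2-fold and 85.6% of those changed 4-fold with 8 false calls. For border against adjacent tissue over 15741 genes it recovered 54.1 and 80.9% with 7 false calls, and for center against border over 15759 genes 63.2 and 70.4% with 5. In the simulated border midpoint contrast over 15779 genes, 56.6 and 87.2% were recovered with 12 false calls. The simulated test among the 3 regions over 15757 genes recovered 69.1 and 81.8% with 12 false calls. For genes placed outside the range of the other regions, over 15743 genes, 53.1 and 85.4% were recovered with 2 false calls. In the simulated center against adjacent tissue comparison, camera, camera with an estimated correlation and fry each called the 1 shifted list of 44 and 0 others. Simulated genes were drawn independently of each other. False calls of lists whose genes move together were therefore not tested. Few genes were changed in each simulation, such as 95 by 2-fold and 97 by 4-fold for center against adjacent tissue. In the real data 7856 genes were called there, and recovery and false calls with that many changed genes were not tested.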

Results

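Gene expression was measured in 3 regions of 1 human primary melanoma, a tumor of pigment cells. The tumor center, the tumor border and the adjacent tissue were each taken from 3 sections, and 9 libraries were sequenced after capture of coding exons. In sections 1 to 3 the center libraries held 15256326, 13707060 and 14085044 counts in genes. The border libraries held 13764825, 11973820 and 12656023, and the adjacent tissue libraries 14588513, 14892339 and 12103771. At this depth 16209 genes were tested, and coordinates were those of GENCODE version 29 on GRCh38. FLG, which encodes the filaggrin precursor of cornified epidermis, took 6.39 to 7.94% of all gene counts in adjacent tissue, 3.44 to 4.35% at the border and 0.153 to 0.388% in the center.

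The first principal component of log2 CPM held 47.2% of the variance and ordered the regions, with the border between the center and adjacent tissue. A second component held 32.3% and crossed the regions. It moved with the share of counts on olfactory receptor genes, which ranged from 40.5 to 450 CPM in the 9 libraries, with both extremes in adjacent tissue. Across all 3 regions, 6849 of 16209 genes (42.3%) differed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

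**Figure D1:**
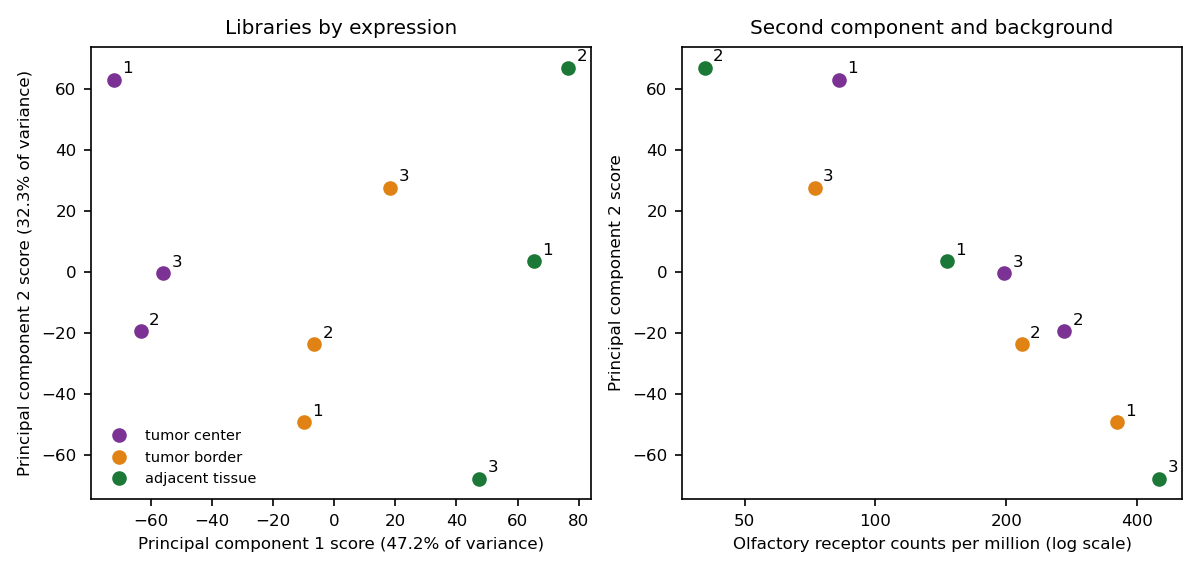
Each point is 1 of the 9 libraries, placed by its scores on the first and second principal components of log2 CPM, which held 47.2 and 32.3% of the variance; colors mark the 3 regions. The first component orders center, border and adjacent tissue, and libraries of each region spread along the second.

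The first comparison asked which genes differed between the tumor center and the tissue next to the tumor. Most tested genes of the lists for pigment cells, neural crest, Schwann cells, macrophages and proliferation rose in the center, and most of those for differentiated keratinocytes, dermal matrix, smooth muscle, T cells and B cells fell. MITF, the master transcription factor of the melanocyte lineage, averaged 735 ± 13.0 CPM (SD, n = 3) in the center and 201 ± 16.1 in adjacent tissue. CDH2, which encodes N-cadherin, rose from 5.02 ± 1.08 to 106 ± 20.3 CPM, and SPP1, which encodes the secreted protein osteopontin, from 3.51 ± 0.414 to 117 ± 9.05 CPM. FLG fell from 72765 ± 12141 to 2726 ± 1143 CPM. MS4A1, which encodes the B cell antigen CD20, fell from 61.9 ± 11.4 to 2.46 ± 0.744 CPM.

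Of the genes with at least 20 CPM in the center and no overlap between libraries, MUC7 had the largest rise, by 5.13 ± 0.45 on the log2 scale (SE), with an adjusted p of 1.41e-05, where variable segments of immunoglobulins and T cell receptors were left aside here and below. It is a mucin gene on chromosome 4 from 70430492 to 70482997 (GRCh38). SPP1, on chromosome 4 from 87975650 to 87983426, rose by 5.06 ± 0.15 with an adjusted p of 7.35e-09. FAM178B rose by 4.86, and CDH2, on chromosome 18 from 27950966 to 28177446, by 4.41 ± 0.25. DLL3, a ligand that inhibits Notch signaling, rose by 4.28 ± 0.53 and lies on chromosome 19 from 39498895 to 39508481. The tubulin gene TUBB2B rose by 3.93 and the matricellular protein gene CCN3 by 3.85. Each of these 7 genes was higher in all 3 center libraries than in any adjacent tissue library.

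Of the genes with at least 20 CPM in adjacent tissue and no overlap between libraries, the largest fall was that of PLA2G2A, a secreted phospholipase gene on chromosome 1 from 19975431 to 19980416, with a log2 fold change of -7.13 ± 0.39 and an adjusted p of 1.87e-07. Its 3 center libraries held 7 counts in all, so the size of this fall rests on few counts. ADH1B, an alcohol dehydrogenase gene on chromosome 4 from 99304964 to 99352760, had a log2 fold change of -6.00 ± 0.42. KRT77, a keratin gene of the sweat gland list on chromosome 12 from 52689626 to 52703463, had -5.81 ± 0.49 and PM20D1 -5.71 ± 1.0. PI16, a marker of resting fibroblasts on chromosome 6 from 36948263 to 36964837, had -5.52 ± 0.25. CCL19, a chemokine that attracts lymphocytes, had -5.50 ± 0.28, the muscle intermediate filament gene DES -5.49 ± 0.57 and the hair follicle and basal keratin gene KRT15 -5.15 ± 0.49.

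Of 20 tested genes of melanocyte lineage and pigmentation, 18 rose, 0 fell and 2 were not called, and 19 rose and 1 fell when adjusted over the list alone. S100B rose by 3.54, the melanosome enzyme gene TYRP1 by 2.76, the endothelin receptor gene EDNRB by 2.34 and SOX10 by 2.36. PMEL averaged 3606 ± 638 CPM in the center and 1127 ± 236 in adjacent tissue, MLANA 609 ± 23.8 and 175 ± 12.7, and TYR, which encodes tyrosinase, 1010 ± 43.6 and 315 ± 18.4. The list had a median log2 fold change of 1.68 and was called by camera (adjusted p = 5.27e-11), with an adjusted p = 0.321 with an estimated correlation. Of 14 neural crest genes 10 rose and 2 fell, with the same counts adjusted over the list alone. FOXD3 rose by 3.05 and NES by 2.41, whereas TFAP2B had a log2 fold change of -2.50 (camera adjusted p = 0.00313, adjusted p = 0.321 with an estimated correlation). Of 10 Schwann cell genes 6 rose and 1 fell, or 6 and 2 adjusted over the list alone, among them CDH19 by 2.92 (camera adjusted p = 0.0186, adjusted p = 0.321 with an estimated correlation).

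Of 24 proliferation genes 21 rose and 0 fell, and the counts adjusted over the list alone were equal. TYMS rose by 1.89 and CENPF by 1.72, while MKI67, the gene of the Ki-67 antigen, was not called at 226 ± 17.1 CPM in the center and 191 ± 30.1 in adjacent tissue. The list was called by camera (adjusted p = 7.89e-09, adjusted p = 0.321 with an estimated correlation). Of 25 oxidative phosphorylation genes 19 rose and 0 fell under both adjustments, over all genes and adjusted over the list alone, and SDHC rose by 1.03 (camera adjusted p = 2.19e-07, adjusted p = 0.325 with an estimated correlation). Of 33 cytosolic ribosomal protein genes, whose counts are uncertain because of near-identical pseudogenes, 28 rose and 1 fell, or 30 and 1 adjusted over the list alone. RPS13 rose by 1.40 and RPL10A by 1.19 (camera adjusted p = 5.39e-09, adjusted p = 0.376 with an estimated correlation). Of 10 heat shock genes 7 rose and 0 fell, with equal counts adjusted over the list alone. HSPD1 rose by 0.64 and HSPE1 by 1.13 (camera adjusted p = 0.0284, adjusted p = 0.325 with an estimated correlation).

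In 3 further tumor lists members went both ways and camera made no call. Of 19 genes of an invasive melanoma state, 11 rose, among them FN1 by 2.64 and TNC by 2.11, and 6 fell, among them EGFR (-2.66) and ZEB1 (-1.71), with equal counts adjusted over the list alone (camera adjusted p = 0.266). Of 14 genes of MAPK pathway output 8 rose, among them DUSP4 by 2.21 and SPRY2 by 2.09, and 3 fell, among them EPHA4 (-2.08), again with equal counts adjusted over the list alone (camera adjusted p = 0.253). Of 21 hypoxia and glycolysis genes 11 rose, among them LDHA by 1.41, and 5 fell, among them PDK1 (-1.23) and VEGFA (-1.05), with equal counts adjusted over the list alone (camera adjusted p = 0.250). Of 10 cancer-testis antigen genes tested, 1 fell and 0 rose by edgeR, or 0 and 0 adjusted over the list alone. The 1 was MAGEA6, and PRAME averaged 3.08 ± 0.223 CPM in the center and 4.01 ± 0.424 in adjacent tissue (adjusted p = 0.257).

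Of 24 genes of differentiated keratinocytes 19 fell and 0 rose, or 19 fell and 1 rose adjusted over the list alone, with a median log2 fold change of -1.81. FLG2 had -4.38, KRT1 -4.03 and KRT10 -3.49 (camera adjusted p = 2.20e-07, adjusted p = 0.412 with an estimated correlation). Of 16 basal keratinocyte genes 10 fell and 1 rose, with equal counts adjusted over the list alone. COL7A1, the collagen of anchoring fibrils, had -3.08 and KRT5 -1.64, while KRT14 was not called at 5892 ± 1861 CPM in the center and 8872 ± 1978 in adjacent tissue (camera adjusted p = 0.000116, adjusted p = 0.481 with an estimated correlation). Among 13 genes of stressed keratinocytes 4 rose and 0 fell, or 0 and 0 adjusted over the list alone, and the list was not called (camera adjusted p = 0.253). The 4 were KRT17, PI3, KRT6C and KRT6B, and KRT6B averaged 8276 ± 2256 CPM in the center and 3794 ± 1564 in adjacent tissue. Keratin genes of this group share near-identical sequence, so their values are uncertain.

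Of 18 fibroblast genes 16 fell and 1 rose, with equal counts adjusted over the list alone. FBLN1 had a log2 fold change of -3.24, DCN of -2.29, COL1A1 of -1.30 and COL3A1 of -1.17 (camera adjusted p = 2.26e-08, adjusted p = 0.321 with an estimated correlation). All 12 genes of elastic fibre and dermal matrix fell, with equal counts adjusted over the list alone and a median of -2.56. TNXB fell from 762 ± 88.6 to 34.8 ± 8.23 CPM, and ELN, the gene of elastin, from 109 ± 6.57 to 7.43 ± 2.07 CPM (camera adjusted p = 2.19e-07, adjusted p = 0.175 with an estimated correlation). Of 19 genes of activated fibroblasts and matrix remodelling 7 rose, among them SULF1 by 2.14, and 7 fell, among them THBS2 (-2.22), with equal counts adjusted over the list alone. The median of this list was 0.03 and the mean 0.21, and camera made no call in the upward direction, while fry gave the downward direction. Of 12 smooth muscle and pericyte genes 11 fell and 0 rose under both adjustments, over all genes and adjusted over the list alone, among them MYH11 (-4.79) and SYNPO2 (-2.78) (camera adjusted p = 3.43e-05, adjusted p = 0.376 with an estimated correlation).

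Of 13 blood endothelial genes 8 fell and 0 rose, or 9 and 0 adjusted over the list alone, among them VWF (-1.04) and CDH5 (-1.16). PECAM1 was not called at 1.24 ± 0.202 CPM in the center and 2.44 ± 0.256 in adjacent tissue (camera adjusted p = 0.00550, adjusted p = 0.321 with an estimated correlation). Of 8 lymphatic endothelial genes 6 fell and 0 rose, with equal counts adjusted over the list alone, among them LYVE1 (-2.26) and MMRN1 (-2.20) (camera adjusted p = 0.0257, adjusted p = 0.321 with an estimated correlation).

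Of 17 T cell genes 16 fell and 0 rose under both adjustments, over all genes and adjusted over the list alone. IL7R had -2.60 and CD3E -1.50 (camera adjusted p = 5.39e-09, adjusted p = 0.321 with an estimated correlation). Of 18 cytotoxic lymphocyte genes 13 fell and 0 rose, with equal counts adjusted over the list alone. GZMK had -1.85, and CD8A averaged 32.1 ± 2.22 CPM in the center and 43.2 ± 5.66 in adjacent tissue (camera adjusted p = 0.000234, adjusted p = 0.175 with an estimated correlation). Of 19 genes of immune checkpoints and regulatory T cells 10 fell and 0 rose, with equal counts adjusted over the list alone. CTLA4 had -1.29 and FOXP3 -1.15, while CD274, which encodes PD-L1, was not called at 11.9 ± 1.93 and 12.9 ± 1.29 CPM (camera adjusted p = 0.0284, adjusted p = 0.321 with an estimated correlation). Of 12 B cell genes 10 fell and 0 rose, with equal counts adjusted over the list alone, led by MS4A1 (-4.65) and CD79A (-3.37) (camera adjusted p = 5.42e-05, adjusted p = 0.321 with an estimated correlation). Of 12 plasma cell genes 6 fell, among them IGHM (-3.45), and 1 rose, with equal counts adjusted over the list alone. The 1 was IRF4, which pigment cells also express (camera adjusted p = 0.0357, adjusted p = 0.590 with an estimated correlation).

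Of 20 macrophage genes 15 rose and 0 fell, with equal counts adjusted over the list alone and a median of 1.29. The scavenger receptor gene MSR1 rose by 2.57 and FCGR2A by 1.77, while CD163 rose by 0.50, from 152 ± 20.0 to 215 ± 19.1 CPM (camera adjusted p = 6.03e-07, adjusted p = 0.321 with an estimated correlation). Of 14 genes of dendritic and Langerhans cells 12 fell and 0 rose, with equal counts adjusted over the list alone. CD207, the Langerhans cell lectin langerin, had -2.88 and CD1C -2.53 (camera adjusted p = 8.24e-06, adjusted p = 0.321 with an estimated correlation). Of 9 mast cell genes 8 fell and 0 rose, with equal counts adjusted over the list alone, among them MS4A2 (-1.83) and HDC (-1.60) (camera adjusted p = 0.000415, adjusted p = 0.321 with an estimated correlation). The leukocyte gene PTPRC averaged 476 ± 40.7 CPM in the center and 991 ± 139 in adjacent tissue. Of 15 genes of MHC class I presentation 9 rose, among them PSMB8 by 1.44 and TAP1 by 1.26, and 3 fell, among them NLRC5 (-1.33). Adjusted over the list alone 9 rose and 4 fell (camera adjusted p = 0.0477, adjusted p = 0.590 with an estimated correlation).

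In all, 7856 of 16209 genes differed between center and adjacent tissue, 3805 of them higher and 4051 lower in the center, and 1354 and 2311 of these differed at least 2-fold. By camera 23 of 44 lists were called, 9 up and 14 down, while 1 split that mixed the regions gave 24. With an estimated correlation camera called 0 lists at an adjusted p under 0.05 and 6 at an unadjusted p under 0.05, while fry called 32. All libraries came from 1 tumor, so p-values over these regions are too small. Without the 4 libraries farthest in olfactory receptor share the count was lower, but only 1 adjacent tissue library was left in that fit.

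**Figure D2:**
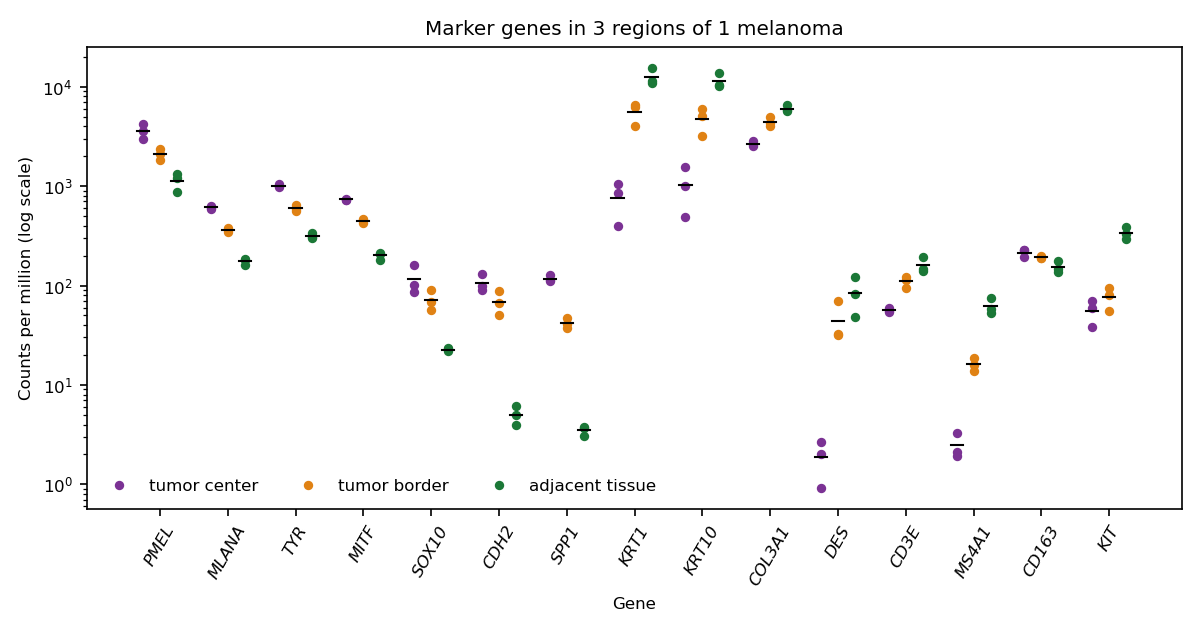
Points are the CPM of each library on a log axis for named genes, with bars at the mean of each region and 3 libraries per region. MITF averages 735 CPM in the center, 447 at the border and 201 in adjacent tissue, and MS4A1 runs the other way at 2.46, 16.2 and 61.9 CPM.

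The second comparison set the tumor border against adjacent tissue. Most tested genes of the lists for pigment cells, Schwann cells, proliferation and macrophages rose at the border, and most of those for T cells, B cells and fibroblasts fell. MITF averaged 447 ± 23.8 CPM (SD, n = 3) at the border and 201 ± 16.1 in adjacent tissue, and rose by 1.16 with an adjusted p of 2.51e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. KIT, which encodes the receptor of stem cell factor in melanocytes and mast cells, fell from 336 ± 48.9 to 76.9 ± 20.1 CPM. It lies on chromosome 4 from 54657918 to 54740715. Of 13 tested blood endothelial genes 0 rose and 0 fell by edgeR, both over all genes and adjusted over the list alone.

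Of the genes with at least 20 CPM at the border and no overlap between libraries, MUC7 had the largest rise, by 4.66 ± 0.45 on the log2 scale, and CDH2 rose by 3.76 ± 0.25. IGHG3, an immunoglobulin constant region gene on chromosome 14 from 105764503 to 105771405, rose by 3.68 ± 0.79. Its border libraries spread widely, at 564 ± 267 CPM. SPP1 rose by 3.57 ± 0.15, DLL3 by 3.39 ± 0.53, the glutamate receptor gene GRIK2 by 3.22 ± 0.30 and CCN3 by 3.16 ± 0.16. Of the genes with at least 20 CPM in adjacent tissue and no overlap between libraries, KIF1A, which encodes a neuronal kinesin, had the largest fall. It lies on chromosome 2 from 240713761 to 240821036, and its log2 fold change was -3.48 ± 0.36 with an adjusted p of 0.000224. PCSK2, a prohormone convertase gene, had -3.04 ± 0.21 and LAMB4 -2.55 ± 0.34. TFAP2B had -2.50 ± 0.17, CDHR1 -2.48 ± 0.20, DNAI3 -2.37 ± 0.14, the Wnt antagonist gene FRZB -2.26 ± 0.24 and KIT -2.13 ± 0.25. KIT and KIF1A fell also in the center against adjacent tissue, with log2 fold changes of -2.60 and -4.23.

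Of 20 pigmentation genes 14 rose and 1 fell, with equal counts adjusted over the list alone, among them S100B by 2.83, TYRP1 by 1.98 and PMEL by 0.89 (camera adjusted p = 4.02e-10, adjusted p = 0.336 with an estimated correlation). Of 14 neural crest genes 9 rose and 2 fell under both adjustments, over all genes and adjusted over the list alone, among the former NES by 2.14 (camera adjusted p = 0.00187, adjusted p = 0.362 with an estimated correlation). Of 10 Schwann cell genes 6 rose and 0 fell, with equal counts adjusted over the list alone, among them CDH19 by 2.43 (camera adjusted p = 0.000275, adjusted p = 0.312 with an estimated correlation). Of 24 proliferation genes 18 rose and 0 fell, again with equal counts adjusted over the list alone, among them CENPF by 1.16 (camera adjusted p = 3.05e-09, adjusted p = 0.336 with an estimated correlation). Of 25 oxidative phosphorylation genes 14 rose and 0 fell, or 17 and 0 adjusted over the list alone (camera adjusted p = 2.83e-07, adjusted p = 0.362 with an estimated correlation). Of 33 ribosomal protein genes 23 rose and 0 fell, or 24 and 0 adjusted over the list alone (camera adjusted p = 4.02e-10, adjusted p = 0.362 with an estimated correlation). Of 10 heat shock genes 2 rose, HSPE1 and HSPD1, and 0 fell, with equal counts adjusted over the list alone (camera adjusted p = 0.0386, adjusted p = 0.362 with an estimated correlation).

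Of 20 macrophage genes 13 rose and 0 fell, or 15 and 0 adjusted over the list alone, among them MSR1 by 2.04 and CD68 by 1.21 (camera adjusted p = 5.36e-08, adjusted p = 0.362 with an estimated correlation). Of 17 T cell genes 15 fell and 0 rose, or 16 and 0 adjusted over the list alone. IL7R had -0.98 and CD3E -0.54 (camera adjusted p = 1.22e-08, adjusted p = 0.362 with an estimated correlation). CD8A averaged 44.0 ± 4.05 CPM at the border and 43.2 ± 5.66 in adjacent tissue (adjusted p = 0.933). Of 18 cytotoxic lymphocyte genes 2 fell, GNLY and GZMK, and 0 rose, with equal counts adjusted over the list alone (camera adjusted p = 0.00572, adjusted p = 0.329 with an estimated correlation). Of 19 genes of checkpoints and regulatory T cells 3 fell and 0 rose, or 0 and 0 adjusted over the list alone. The 3 were CTLA4, FOXP3 and BTLA (camera adjusted p = 0.0403, adjusted p = 0.362 with an estimated correlation). Of 12 B cell genes 7 fell and 0 rose, or 9 and 0 adjusted over the list alone, led by MS4A1 with -1.94 (camera adjusted p = 2.58e-06, adjusted p = 0.347 with an estimated correlation). Of 14 dendritic and Langerhans cell genes 7 fell and 0 rose, or 10 and 0 adjusted over the list alone, among them CD207 with -1.47 (camera adjusted p = 8.13e-06, adjusted p = 0.336 with an estimated correlation).

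Of 18 fibroblast genes 12 fell and 2 rose, or 14 and 2 adjusted over the list alone, among them SFRP2 with -0.79 and FBLN1 with -0.90 (camera adjusted p = 1.31e-06, adjusted p = 0.362 with an estimated correlation). Of 12 elastic fibre genes 7 fell and 0 rose, or 8 and 0 adjusted over the list alone, among them TNXB with -1.49 (camera adjusted p = 8.90e-07, adjusted p = 0.312 with an estimated correlation). Of 16 basal keratinocyte genes 5 fell and 1 rose, or 8 and 1 adjusted over the list alone, among them COL17A1 with -1.74 (camera adjusted p = 4.69e-05, adjusted p = 0.509 with an estimated correlation). Of 24 differentiated keratinocyte genes 6 fell and 0 rose, or 9 and 0 adjusted over the list alone, among them KRT1 with -1.17 (camera adjusted p = 2.63e-05, adjusted p = 0.563 with an estimated correlation). Sebaceous gland genes were called up by camera (adjusted p = 0.000524, adjusted p = 0.545 with an estimated correlation) with a median of 0.68, although only 2 of 14, ELOVL5 and FAR2, rose, 0 fell and the counts adjusted over the list alone were equal. The sebaceous gland makes the lipid film of skin, and ELOVL3, which elongates its fatty acids, averaged 15.6 ± 4.85 CPM at the border and 7.71 ± 4.01 in adjacent tissue (adjusted p = 0.104). Adjacent tissue libraries were uneven here, as the lowest held 44 of 327 counts for ELOVL3 and 486 of 3139 for KRT79. ELOVL5 and FAR2 were more even, with 559 of 2157 and 196 of 835 counts in the lowest library. Whether the rise reflects glands missed in an adjacent piece was not tested. For hair follicle genes, of which 4 of 14 fell and 0 rose with equal counts adjusted over the list alone, the median was 0.61 and the mean 0.14 while camera gave the downward direction without a call (adjusted p = 0.710).

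In all, 3453 genes differed between border and adjacent tissue, 1953 higher and 1500 lower at the border, and 498 and 291 of these differed at least 2-fold. By camera 18 of 44 lists were called, 9 up and 9 down, while with an estimated correlation camera called 0 at an adjusted p under 0.05 and 6 at an unadjusted p under 0.05, and fry called 20. The highest camera count from a split that mixed the regions was 19 lists. Without adjacent tissue library 1 the count of genes was 1591, and without border library 2 it was 1863. P-values over regions of 1 tumor are too small here as well. Without the 4 libraries farthest from the others in olfactory receptor share the count was lower, but that fit set 1 border library against 1 adjacent tissue library. The loss of replicates alone could lower it.

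**Figure D3:**
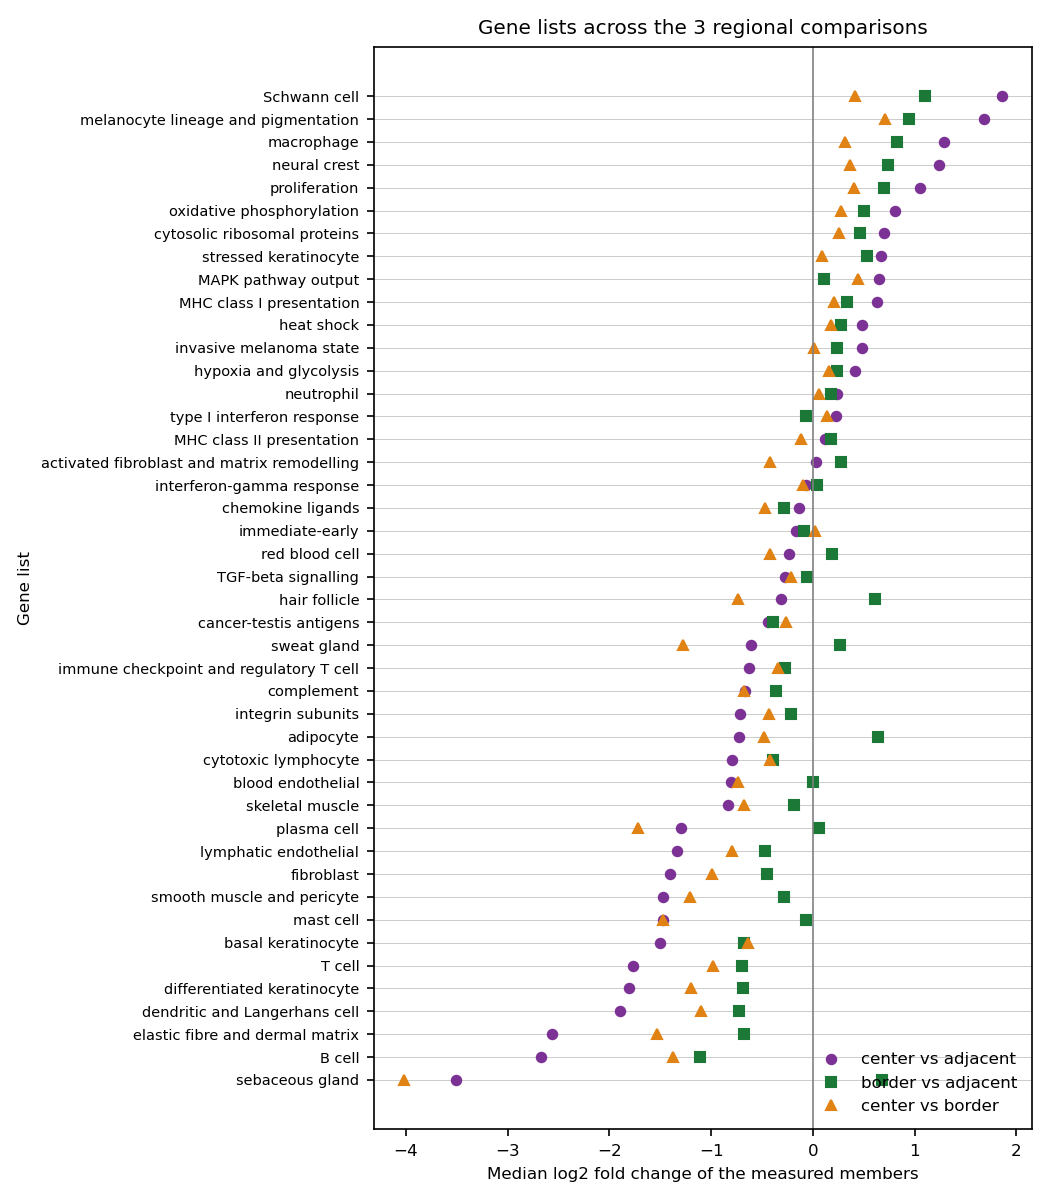
For each gene list the points give the median log2 fold change of its tested members in the 3 pairwise comparisons of regions. The melanocyte list lies at 1.68 for center against adjacent tissue and 0.71 for center against border, and the B cell list at -2.67 and -1.37.

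The third comparison set the tumor center against the tumor border. Falls of at least 2-fold in the center were far more frequent than rises of that size, and of the 8 genes named for the largest falls 3 were on the sebaceous gland list and 2 on the smooth muscle list. Border RNA made in part of center RNA would by itself limit rises from border to center, and not falls. The excess of falls was not tested against such a mixture. GAL, a neuropeptide gene on the sebaceous list, averaged 27.4 ± 6.25 CPM (SD, n = 3) at the border and 0.214 ± 0.189 in the center. KRT79, a keratin of sebaceous ducts, averaged 135 ± 38.1 and 4.42 ± 3.56 CPM. MITF was higher in the center at 735 ± 13.0 against 447 ± 23.8 CPM, and rose by 0.72 with an adjusted p of 0.000639 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. SPP1 rose from 41.7 ± 4.68 to 117 ± 9.05 CPM.

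Of the genes with at least 20 CPM in the center and no overlap between libraries, SPP1 had the largest rise, by 1.49 ± 0.12 on the log2 scale with an adjusted p of 2.57e-05. After it came the transcription factor gene MSC with 0.99 ± 0.15, BAMBI, an inhibitor of TGF-beta signaling, with 0.97 ± 0.14 and S100A1 with 0.96 ± 0.17. TSPAN10 rose by 0.95, the melanosome transporter gene SLC45A2 by 0.94, TUBB4A by 0.94 and the transcription factor gene TBX2 by 0.93. Of the genes with at least 20 CPM at the border and no overlap between libraries, GAL, on chromosome 11 from 68683779 to 68691175, had the largest fall at -6.93 ± 0.76 with an adjusted p of 0.000712, and its 3 center libraries held 9 counts in all. PM20D1 had a log2 fold change of -6.00 ± 1.0. KRT79, on chromosome 12 from 52821410 to 52834295, had -4.93 ± 0.61, the lipoxygenase gene ALOX15B -4.77 ± 0.70 and DES -4.56 ± 0.56. ACSBG1 had -4.14 ± 0.53, ADH1B -4.11 ± 0.42, and MYH11, the myosin heavy chain of smooth muscle, fell by 4 ± 0.40.

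Of 14 sebaceous gland genes 12 fell and 0 rose, with equal counts adjusted over the list alone and a median of -4.02. ELOVL3 had -5.32 and AWAT2, a wax synthase gene with 6 counts in the 3 center libraries, -6.16 (camera adjusted p = 6.48e-06, adjusted p = 0.325 with an estimated correlation). All 12 smooth muscle and pericyte genes fell, with equal counts adjusted over the list alone (camera adjusted p = 9.96e-09, adjusted p = 0.285 with an estimated correlation). Of 18 fibroblast genes 16 fell and 1 rose, with equal counts adjusted over the list alone, among them SFRP2 with -2.23 and COL3A1 with -0.74 (camera adjusted p = 4.15e-13, adjusted p = 0.255 with an estimated correlation). Of 12 elastic fibre genes 9 fell and 0 rose, or 11 and 0 adjusted over the list alone, among them ELN with -3.20 (camera adjusted p = 1.69e-09, adjusted p = 0.127 with an estimated correlation). Of 19 activated fibroblast genes 6 fell, among them THBS2 with -1.45, and 3 rose, or 8 and 3 adjusted over the list alone (camera adjusted p = 0.0358, adjusted p = 0.285 with an estimated correlation). Of 24 differentiated keratinocyte genes 14 fell and 0 rose, or 16 and 0 adjusted over the list alone, among them FLG with -3.87 (camera adjusted p = 3.11e-09, adjusted p = 0.325 with an estimated correlation). Of 16 basal keratinocyte genes 7 fell and 0 rose, or 7 and 1 adjusted over the list alone, among them TP63 with -1.62 (camera adjusted p = 0.000202, adjusted p = 0.405 with an estimated correlation). Of 9 sweat gland genes tested 1 fell, KRT77, and 0 rose, or 5 and 0 adjusted over the list alone (camera adjusted p = 0.00749, adjusted p = 0.321 with an estimated correlation).

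Of 20 pigmentation genes 16 rose and 0 fell, or 19 and 0 adjusted over the list alone, with a median of 0.71. MLANA rose by 0.76 and TYR by 0.76, while SOX10 had a log2 fold change of 0.69 and was not called (adjusted p = 0.0681). The list was called by camera (adjusted p = 3.44e-15, adjusted p = 0.187 with an estimated correlation). Of 14 neural crest genes 6 rose and 0 fell, or 6 and 1 adjusted over the list alone, among them FOXD3 by 0.90 (camera adjusted p = 0.000721, adjusted p = 0.285 with an estimated correlation). For Schwann cell genes, of which 3 of 10 rose and 1 fell, or 5 and 2 adjusted over the list alone, the median was 0.41 and the mean -0.15 (camera adjusted p = 0.111). Of 24 proliferation genes 6 rose and 0 fell, with equal counts adjusted over the list alone, among them TYMS by 0.82 (camera adjusted p = 1.18e-06, adjusted p = 0.285 with an estimated correlation). Of 25 oxidative phosphorylation genes 3 rose and 0 fell, with equal counts adjusted over the list alone (camera adjusted p = 1.33e-05, adjusted p = 0.325 with an estimated correlation). Of 33 ribosomal protein genes 2 rose and 0 fell, or 0 and 0 adjusted over the list alone (camera adjusted p = 1.40e-05, adjusted p = 0.412 with an estimated correlation). Of 21 type I interferon response genes 4 rose, among them IFI27 by 0.61 and ISG15 by 0.72, and 0 fell, with equal counts adjusted over the list alone (camera adjusted p = 0.00639, adjusted p = 0.412 with an estimated correlation). Of 15 genes of MHC class I presentation 4 rose and 1 fell, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.0376, adjusted p = 0.495 with an estimated correlation).

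Of 20 macrophage genes 6 rose and 0 fell, or 7 and 0 adjusted over the list alone, among them VSIG4 by 0.72 (camera adjusted p = 7.36e-05, adjusted p = 0.325 with an estimated correlation). T cell genes fell in 16 of 17 cases and rose in 0, with equal counts adjusted over the list alone, among them IL7R with -1.62 (camera adjusted p = 2.24e-10, adjusted p = 0.285 with an estimated correlation). Of 12 B cell genes 6 fell and 0 rose, or 9 and 0 adjusted over the list alone, led by MS4A1 with -2.71 (camera adjusted p = 3.76e-05, adjusted p = 0.285 with an estimated correlation). Plasma cell genes fell in 5 of 12 cases, among them FCRL5 with -1.68, and 1 rose, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.000202, adjusted p = 0.325 with an estimated correlation). Of 9 mast cell genes 8 fell and 0 rose, with equal counts adjusted over the list alone, among them CPA3 with -1.49 (camera adjusted p = 1.18e-06, adjusted p = 0.180 with an estimated correlation). Of 18 cytotoxic lymphocyte genes 7 fell and 0 rose, with equal counts adjusted over the list alone, and CD8A had -0.45 (camera adjusted p = 0.000696, adjusted p = 0.180 with an estimated correlation). Of 14 dendritic and Langerhans cell genes 8 fell and 0 rose, or 11 and 0 adjusted over the list alone, among them CLEC10A with -1.42 (camera adjusted p = 9.25e-06, adjusted p = 0.285 with an estimated correlation). Blood endothelial genes fell in 6 of 13 cases and rose in 0, or 10 and 0 adjusted over the list alone, and VWF had -1.04 (camera adjusted p = 2.82e-05, adjusted p = 0.255 with an estimated correlation). Lymphatic endothelial genes fell in 3 of 8 cases and rose in 0, or 6 and 0 adjusted over the list alone, and MMRN1 had -1.50 (camera adjusted p = 0.0138, adjusted p = 0.287 with an estimated correlation).

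In all, 2811 genes differed between center and border, 943 higher and 1868 lower in the center, and 13 and 1054 of these differed at least 2-fold. With DESeq2 size factors 1340 were higher and 1695 lower, so the share of higher genes was 44.2% in place of 33.5%. By camera 26 of 44 lists were called, 8 up and 18 down, while with an estimated correlation camera called 0 at an adjusted p under 0.05 and 7 at an unadjusted p under 0.05, and fry called 26. A split that mixed the regions gave up to 27 lists by camera. Without border library 3 the count of genes was 1189. It was lower also without the 4 libraries farthest in olfactory receptor share, but that fit kept only 1 border library. These p-values too are over regions of 1 tumor and are too small.

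The last question was where the border lay between the other regions. Among the 7856 genes that differed between center and adjacent tissue, the border mean lay between the other means for 7551 (96.1%). On the log2 scale the border stood at a median of 0.526 ± 0.050 (SD, n = 3 border libraries) of the way from adjacent tissue to center, with libraries 1 to 3 at 0.541, 0.566 and 0.470. Set against center and adjacent tissue of the same section, for the same genes, they stood at 0.516, 0.542 and 0.519, or 0.526 ± 0.014. These genes were chosen for a large difference, so the position is a description and was not tested.

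Against the midpoint of the log2 levels of center and adjacent tissue, 178 genes differed at the border by edgeR's quasi-likelihood test, 165 above and 13 below. Of those above, the largest differences among genes with at least 20 CPM in a region and all 3 border libraries on 1 side were GAL at 3.95 ± 0.50 above the midpoint, KRT79 at 2.90, ALOX15B at 2.85, PLA2G2A at 2.32 and ACSBG1 at 2.30, of which GAL, KRT79 and ACSBG1 are on the sebaceous list. PLA2G2A averaged 10.4 ± 2.88 CPM at the border, 0.167 ± 0.149 in the center and 24.8 ± 1.74 in adjacent tissue. Its place above the log2 midpoint rests on 7 counts in the 3 center libraries. Adjacent tissue libraries spread widely for GAL (13.9 ± 9.62 CPM) and KRT79 (73.4 ± 33.4 CPM). CHI3L1, which encodes the secreted glycoprotein YKL-40, averaged 47.4 ± 12.9 CPM at the border, 4.28 ± 1.13 in the center and 27.6 ± 9.49 in adjacent tissue (n = 3 each). Below the midpoint lay PCSK2 (-1.62), DNAI3 (-1.53), TFAP2B (-1.25), PLPPR4 (-0.97), ARNT2 (-0.85) and APBA2 (-0.77). TFAP2B averaged 7.73 ± 0.553 CPM at the border, 7.72 ± 1.69 in the center and 43.8 ± 4.61 in adjacent tissue. Without border library 2 the count was 57 and without border library 3 it was 75, whereas the DESeq2 test gave 321 and olfactory receptor share as a covariate 268. The p-values are over sections of 1 tumor and are too small. The count was lower without the 4 libraries farthest in olfactory receptor share, a fit with 1 border and 1 adjacent tissue library.

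At the border 40 genes lay outside the range of both other regions, 31 above and 9 below. Among those with at least 20 CPM and no overlap between libraries the highest was the immunoglobulin constant region gene IGHG4, at 193 ± 101 CPM at the border, 27.2 ± 26.0 in the center and 32.6 ± 7.09 in adjacent tissue. INSIG1, a regulator of sterol synthesis, averaged 20.4 ± 6.31 CPM at the border, 9.65 ± 0.391 in the center and 10.0 ± 2.27 in adjacent tissue. The matrix genes LTBP2, COMP and COL12A1 followed, with COMP at 112 ± 13.1, 71.7 ± 16.2 and 68.6 ± 12.3 CPM and COL12A1 at 318 ± 37.1, 238 ± 27.1 and 180 ± 14.0 CPM in the same order, and ITGBL1 stood at 52.4 ± 8.26 CPM at the border. Below both regions lay DNAI3, MCOLN3, SLC1A4, FHOD3, VEPH1 and CYTH3, with FHOD3 at 36.3 ± 2.69 CPM against 61.6 ± 1.78 and 49.3 ± 2.60. The count was 23 without adjacent tissue library 1, 21 without center library 2, 18 without border library 2 and 21 without border library 3. It was 62 with olfactory receptor share as a covariate. The count was lower without the 4 libraries farthest in that share, a fit with 1 border and 1 adjacent tissue library. These p-values are again over sections of 1 tumor and too small.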

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

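Of the tests in this part, those on bitter taste receptors, on library size and on a mixture at the border were chosen before their results were seen. The tests on olfactory receptors, on other silent gene families, on sections, on records outside genes, on pigment genes, on center genes scarce in adjacent tissue, on KIT and mast cells, on genes outside the range of both other regions, on genes called against both the midpoint and the mixture, on the size of differences left against the mixture and the counts of splits were chosen after.

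Records that no gene took up stood out as a signal outside the main measurement, because their share in the center lay above that in adjacent tissue. Their share was 8.59 ± 1.28% (SD, n = 3) in the center, 7.49 ± 2.32% at the border and 6.32 ± 0.537% in adjacent tissue, with an exact permutation p of 0.100 for center against adjacent tissue, the smallest that 3 against 3 libraries can give. Records falling in more than 1 gene stood out for the same reason, at 1.96 ± 0.0651% in the center, 1.68 ± 0.0854% at the border and 1.38 ± 0.104% in adjacent tissue, with the same exact permutation p of 0.100.

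The second component of variation, with 32.3% of the variance, separated libraries within regions, and reads over genes that the tissue does not express may account for it. Recomputed without olfactory receptor genes, it had a Pearson r of -0.96 with their log2 share (permutation p = 3.31e-05, adjusted p = 5.79e-05 over 7 relations and 9 libraries; Spearman rho -0.97, p = 0.000165, adjusted p = 0.000289; r = -0.98 without the 2 farthest libraries), and the lowest r of that share with keratin-associated, interferon alpha and PRAME family genes was 0.95. For the share of records outside genes the r of deviations within regions was 0.78 (exact permutation p = 0.00463), but over all 9 libraries r was 0.68 (adjusted permutation p = 0.0650, and r = 0.37 without the 2 farthest). Bitter taste receptors gave an r of 0.17 with olfactory receptor share. That value met the bound set beforehand against a background shared by silent gene families, so this prediction failed. Only afterwards was it seen that 6 of their 24 genes held 76.3% of the family's counts. The same was not examined in the families chosen later, and whether those are silent in this tissue was not tested. Sections held 4.93% of the variance of the axis, which argues against them, while library size (r = 0.66, permutation p = 0.0557) cannot be told apart at 9 libraries. Regions held 7.22% of the axis, and no biological explanation was tested.

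At the border 165 genes lay above and 13 below the log2 midpoint, and a linear mixture of center and adjacent RNA could give such an excess, because the mean of mixed RNA lies above the midpoint of log2 levels. Against a mixture with a center share of 0.54 (a share of 0.4 was recovered as 0.395 in simulated data), 30 calls were left in place of 178, 18 above and 12 below, and at an unadjusted p under 0.05 the counts went from 1100 above and 173 below to 501 and 317. Of the 165 genes 88 kept more than 50% of their difference, with a median of 1.04 before and 0.54 after, and the highest p that was called fell from 0.000533 to 7.70e-05, so calls ended in part through the stricter threshold: GAL went from 3.95 ± 0.50 (SE) to 2.83 ± 0.52 (adjusted p = 0.126) and KRT79 from 2.90 ± 0.43 to 1.96 ± 0.43 (adjusted p = 0.225), while CHI3L1 stayed called (adjusted p = 0.0333). PLA2G2A kept less, going from 2.32 ± 0.28 to 0.79 ± 0.31. A mixture cannot place a gene outside the range of both regions, so it is argued against for the 28 midpoint calls that lay there, among them COL12A1 (0.62 ± 0.10 before and 0.59 ± 0.10 after). In the same direction 26 midpoint calls were still called against the mixture, among them TFAP2B (-1.25 ± 0.15 and -1.63 ± 0.15, adjusted p = 0.000852). That test used a share of 0.54 for all genes, so it argues only against this common share. For the 12 of the 26 not called outside the range, a mixture at another share was not tested and stays open. Together the 28 and the 26 make 40 genes. For the other 138 a mixture and a border tissue of its own cannot be told apart, because the genes were chosen for large differences.

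The 18 pigment genes that rose in the center stood in adjacent tissue at a median of 30.0% of their center level, from 8.59% for S100B to 67.1% for RAB27A. Tumor RNA carried into adjacent tissue at 1 share would set a floor there for every gene of the center. Of 6524 genes with at least 20 CPM in the center, 30 had all 3 adjacent libraries below 50% of the level that the median share would need, among them CCN3 (436 ± 30.8 CPM in the center and 30.2 ± 6.29 in adjacent tissue, or 6.93%), TUBB2B (6.58%) and SPP1 (2.99%), which argues against a share of that size. A share small enough for these 30 genes could contribute, but by itself it would not give the pigment median of 30.0%. Its size was not tested. Pigment cells of skin in adjacent tissue could also contribute, and KIT, which they express, was lower in the center (log2 fold change -2.60). Mast cells make KIT as well, but against adjacent tissue KIT had -2.13 at the border where 9 mast cell genes had a median of -0.07, which argues against them there, and the origin still cannot be told apart because tumor cells with more KIT were not tested.

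For the difference among the 3 regions, 6849 genes were called in the real grouping and 3311 in the highest of the other splits. Of 100 splits only the real grouping itself reached that count, the smallest share that 100 splits can give. This argues against chance but does not exclude it. For the border midpoint (178) and for genes outside the range (40), 2 of 100 splits reached each count, but these splits do not test a border effect, because most of them mix center and adjacent tissue libraries, whose difference then enters the spread within groups. The highest other split gave 4324 and 1403 genes and put the 3 center libraries in the place of the border, which points to a structure of the samples. The 10 splits of 6 libraries are too few for a share under 0.05. The real counts there were 7856, 3453 and 2811 genes for center against adjacent tissue, border against adjacent tissue and center against border, with 0 by edgeR in the highest other split of each. For gene lists the real counts were 23, 18 and 26 and the highest others 24, 19 and 27, and 2, 3 and 2 of the 10 splits gave as many. The number of lists that camera called therefore did not set the real grouping apart from groupings that mixed the regions.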

How the results depend on the processing

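Of the alternatives in this part, those on olfactory receptor share, called background here, were chosen after the data had been seen, and the others before. With section number as a replicate block the counts were 6868 genes among the 3 regions, 7793 for center against adjacent tissue, 3719 for border against adjacent tissue, 3003 for center against border, 171 for the border midpoint and 46 outside the range. The block gave 23, 18 and 26 lists and moved no count by over 1.5 times. For libraries of the same section, correlations of their deviations from region means ran from -0.73 to 0.30. Among libraries of the other regions, 2 of 9 libraries were closest to their own section. Deviations within 3 libraries per region cannot show whether sections share more than a number. The border position spread less against values of the same section, with an SD of 0.014 in place of 0.050.

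Leaving out each library in turn gave 5098 to 6799 genes among the 3 regions, 6287 to 7443 for center against adjacent tissue, 1591 to 2769 for border against adjacent tissue, 1189 to 2921 for center against border, 57 to 232 for the border midpoint and 18 to 46 outside the range. Lists ranged over 21 to 25, 17 to 21 and 22 to 29. The count for border against adjacent tissue was lowest without adjacent tissue library 1 (1591) and was 1863 without border library 2, and that for center against border was lowest without border library 3 (1189). The midpoint count was 57 without border library 2 and 75 without border library 3. Genes outside the range numbered 23 without adjacent tissue library 1, 21 without center library 2, 18 without border library 2 and 21 without border library 3. Of single genes, HBD reversed for tumor center vs adjacent tissue, from -0.35 in all libraries to 2.66 without adjacent tissue library 3, and its range was -0.90 to 2.66. Fewer libraries enter these fits, and beyond that the cause was not tested.

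With background as a covariate the midpoint count was 268 and the count outside the range 62. Without the 4 libraries farthest in background, which leaves 1 border and 1 adjacent tissue library that are assumed to vary like the center, the counts were 3357, 4644, 299, 241, 29 and 6 in the order of the block values. The DESeq2 test gave 321 at the midpoint. An adjusted p under 0.01 gave 1684 for border against adjacent tissue, 1327 for center against border, 60 at the midpoint and 9 outside the range, fewer by construction. With an estimated inter-gene correlation camera called 0, 0 and 0 lists (6, 6 and 7 at an unadjusted p under 0.05; fry 32, 20 and 26), and with background added 0, 0 and 1, the last being elastic fibre and dermal matrix, tumor center vs tumor border (adjusted p = 0.0436). Apart from the correlation and the construction of these alternatives, the cause was not tested. At 11973820 to 15256326 counts, folds of genes with under 10 counts in the center are imprecise.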

Other observations

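The tests in this part were those of the design, and genes outside the rule for named genes were chosen after their values were seen.

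Beyond the groups above, complement genes went both ways in the center against adjacent tissue. CLU had a log2 fold change of -4.25, CFD of -3.52 and C1S of -1.64, whereas CD59, which protects cells from complement, rose by 2.15. Of 19 complement genes 5 rose and 9 fell, or 6 and 9 adjusted over the list alone, without a call (camera adjusted p = 0.171). For center against border 1 rose and 9 fell, or 5 and 10 adjusted over the list alone, and camera called the list down (adjusted p = 0.0213, adjusted p = 0.325 with an estimated correlation). Of 17 chemokine genes 3 rose, among them CCL8 by 1.76, and 6 fell, among them CCL27 (-5.76, with 13 counts in the 3 center libraries) and CXCL12 (-2.66), with equal counts adjusted over the list alone (camera adjusted p = 0.266). Of 20 immediate-early genes 4 rose, among them MYC by 1.13, and 8 fell, among them KLF4 (-1.89), with equal counts adjusted over the list alone (camera adjusted p = 0.362). Of 17 integrin genes 5 rose, among them ITGAV by 1.27, and 8 fell, among them ITGA8 (-2.21), or 6 and 9 adjusted over the list alone (camera adjusted p = 0.351). Of 18 TGF-beta signaling genes 5 rose, among them BAMBI by 1.69 and TGFBR2 by 1.51, and 6 fell, among them LTBP1 (-1.52), or 5 and 7 adjusted over the list alone (camera adjusted p = 0.617).

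Interferon and antigen presentation genes also diverged within their lists in that comparison. WARS1 rose by 1.85 and GBP2 by 1.32, while CXCL9 had -1.51 and IRF8 -1.17, and of 14 interferon-gamma response genes 4 rose and 6 fell, with equal counts adjusted over the list alone. Its median was -0.07 with no call by camera, and fry gave the upward direction. Of 21 type I interferon genes 7 rose and 2 fell, with equal counts adjusted over the list alone (camera adjusted p = 0.158). Of 13 MHC class II genes HLA-DRA rose by 0.39 and CIITA, the activator of these genes, had -1.33, or 0 rose and 1 fell adjusted over the list alone. The median of that list was 0.12 and its mean -0.12, and camera made no call (adjusted p = 0.892) in the upward direction, whereas fry gave the downward one. Among 7 neutrophil genes FPR1 rose by 1.79 and CXCL8 by 2.34 and CXCR2 had -1.08, or 1 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.578).

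Markers of other tissue also differed between center and adjacent tissue without a call for their list. Sebaceous gland genes fell in 11 of 14 cases and rose in 2, or 12 and 2 adjusted over the list alone (camera adjusted p = 0.0643), and skeletal muscle genes fell in 5 of 10 and rose in 0, with equal counts adjusted over the list alone, among them TTN with -2.06 (camera adjusted p = 0.0561). For center against border 3 skeletal muscle genes fell and 0 rose, with equal counts adjusted over the list alone, and the list was called down (camera adjusted p = 0.0213, adjusted p = 0.412 with an estimated correlation). Adipocyte genes fell in 4 of 7 cases, sweat gland genes in 2 of 9, red blood cell genes in 2 of 6 and hair follicle genes in 4 of 14, where 1 rose. Adjusted over the list alone 4, 1, 2 and 4 fell (camera adjusted p = 0.362, 0.228, 0.617 and 0.506). Of all 16209 genes tested, 4051 fell in the center against adjacent tissue. The counts for sweat gland, red blood cell and hair follicle genes lie near that share and do not set these lists apart.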
